A study of Homo sapiens with 32 samples.

How the data were processed

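Expression was measured on Affymetrix HG-U133 Plus 2.0 arrays, which read each gene with 1 or more probe sets, in 24 H1299 and 8 A549 samples. Total RNA was labelled with a 3' in vitro transcription kit. The deposited values are RMA expression per probe set, in the unit intensity on a linear scale, and per the submitters' processing notes RMA and limma were used, with versions not given in the sources used here. A genome build is not given in the sources used here and no coordinates were used. Quantiles of the 2 lines differed (array medians 26.4 to 27.3 in H1299 and 40.1 to 41.2 in A549), so each line was fitted alone. The design had assumed log2 values; the values were linear, so log2 was taken with no pseudocount. All 32 arrays were used.

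Of 54675 probe sets, 41097 had 1 gene symbol, 1801 several and 11777 none, and 54 of the first had a symbol absent from the reference gene table (assembly GRCh38.p14), which was used only for names and for the chromosome of a gene. For each of 19775 genes the probe set with the highest mean log2 value over all arrays was kept, and the 14695 genes (74.3%) with log2 over 5 in at least 3 arrays were tested. Genes without a symbol in the probe table are not named here, and probe sets with no symbol or several were fitted apart, as a count only. In H1299 precision was read from replicates: their correlation was 0.9976 to 0.9988 and the median residual SD 0.0703 log2. In A549, with no replicate, the median residual SD of 0.108 is the departure from the additive fit on 3 degrees of freedom. The 3' to 5' log2 differences of the ACTB control probe sets averaged 0.247 with shLuc and 0.237 with S2sh7 in H1299, and 0.209 and 0.191 in A549.

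H1299 was fitted in limma 3.58.1 (R 4.3.3, the data.table package in version 1.17.8, jsonlite 2.0.0) with 1 mean per group over 8 groups, default eBayes and Benjamini-Hochberg adjustment, and genes were called at adjusted p under 0.05. Contrasts were S2sh7 against shLuc for each cDNA, the difference of that effect between each SMARCA2 cDNA and GFP, BRD or ATPdead against WT under S2sh7, and each cDNA against GFP under shLuc. A549 was fitted with additive terms for cDNA and shRNA over its 8 arrays. The effect that remained with each cDNA was the median over genes called with GFP, tested with fry, and a score per array compared by an exact permutation test. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

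Camera was run on 19 gene lists, of which 18 are given: SWI/SNF subunits, DNA replication, mitosis, inflammatory secreted, extracellular matrix, epithelial, mesenchymal, actin cytoskeleton, YAP and TAZ targets, immediate early, interferon, cholesterol, stress response, NRF2 targets, hypoxia and glycolysis, neuroendocrine, alveolar, and markers of leukocytes and endothelium. The remaining list is not used here, but stays in the adjustment. The lists were tested with camera at a preset correlation of 0.01 on moderated t statistics, adjusted over the lists of a contrast, and again with an estimated correlation. The second test also rests on the residual degrees of freedom of the fit, 16 in H1299 and 3 in A549. A call lost in it need not be lost through the correlation. Groups, contrasts, lists, alternatives and the rule for naming genes were chosen before the data were examined.

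Named genes were SMARCA2 and SMARCA4; the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap (in A549, the same sign in 4 pairs) for the GFP knockdown in H1299 and the A549 knockdown, and 4 and 4 for other comparisons; up to 4 called members with the smallest adjusted p of each list with 3 called members or a camera call; and up to 8 per direction called in both lines. A gene named in 1 comparison was followed in others.

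Alternatives were the mean of all probe sets of a gene, each probe set on its own, no filter, a filter of log2 over 6, repeated quantile normalization, centring of each array, eBayes with trend and robust, array weights, only the arrays compared, a block for replicate number, a 2-fold threshold, other gene choices for the remaining effect, and leaving out each array (in A549 each pair). The calls were tested on simulated data: of genes shifted by 0.5 log2, 93.9% were recovered for the GFP knockdown, 84.8% for the interaction with WT and 51.5% for A549. Each called count was set beside the counts of other splits of the same arrays, all splits where there were 10 or fewer and 100 drawn at random for interactions.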

Results

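Gene expression was measured on 32 arrays from 2 human lung cancer lines, H1299 and A549, both known to carry inactivating changes of SMARCA4. SMARCA2 and SMARCA4 are the alternative ATPase subunits of the SWI/SNF complexes, which slide and evict nucleosomes. Cells carried a short hairpin RNA (shRNA) against SMARCA2, S2sh7, or against luciferase, shLuc. They also expressed GFP, or a wild-type (WT), bromodomain mutant (BRD) or ATPase dead (ATPdead) cDNA, of SMARCA2 in H1299 and of SMARCA4 in A549. Each of the 8 H1299 groups had 3 arrays, labelled biological replicates, and each of the 8 A549 groups had 1. The labels do not say whether replicates came from separate infections or cultures, so p-values measure only the spread between these samples. The number of arrays limits the precision of every comparison.

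SMARCA2 RNA fell with S2sh7 in both lines in every tested probe set except a dim one. That exception gave -0.11 log2 in H1299 with GFP and 0.0002 in A549 over the 4 cDNAs (limma adjusted p = 0.514 and 0.998). In H1299 with GFP, a probe set that no cDNA raised dropped from an intensity of 70.6 (SD 7.01, n = 3) to 28.8 (SD 3.73, n = 3), which was 40.7% of the control; the lower reading lay under log2 5 (4.84), near background, so what remained may have been less. In A549 with GFP the same probe set read 292 with shLuc and 32.4 with S2sh7 (n = 1 each). Another SMARCA2 probe set rose with each SMARCA2 cDNA in H1299 with shLuc, from an intensity of 42.6 with GFP to 121 with WT, 107 with BRD and 109 with ATPdead (adjusted p = 4.75e-05, 1.78e-04 and 7.05e-04). It fell with S2sh7 in the cDNA lines as well, by -0.67, -0.68 and -0.95 log2. In A549 a SMARCA4 probe set read log2 4.56 with shLuc and GFP, and 6.64, 6.91 and 6.85 with shLuc and WT, BRD and ATPdead SMARCA4. With S2sh7 it read 4.97, 7.88, 7.91 and 7.24 in the same order. Of the 7 SMARCA4 probe sets bright enough to be tested, 4 fell with S2sh7 in H1299 with GFP. They included the probe set with the highest mean (log2 fold change -0.60, SE 0.066, adjusted p = 7.46e-07), and the smallest of these falls was -0.29 (adjusted p = 0.00276). These 4 were the brightest of the 7 with shLuc and GFP. The other 3 were not called (-0.06, -0.003 and 0.04, adjusted p = 0.55, 0.976 and 0.715); their intensities with shLuc and GFP were 33.8, 56.6 and 13.0, and the first and the last, near or under log2 5, could hardly have shown a fall. Which part of each transcript these probe sets read is not given in the sources used here, so endogenous and cDNA transcripts were not separated.

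**Figure D1:**
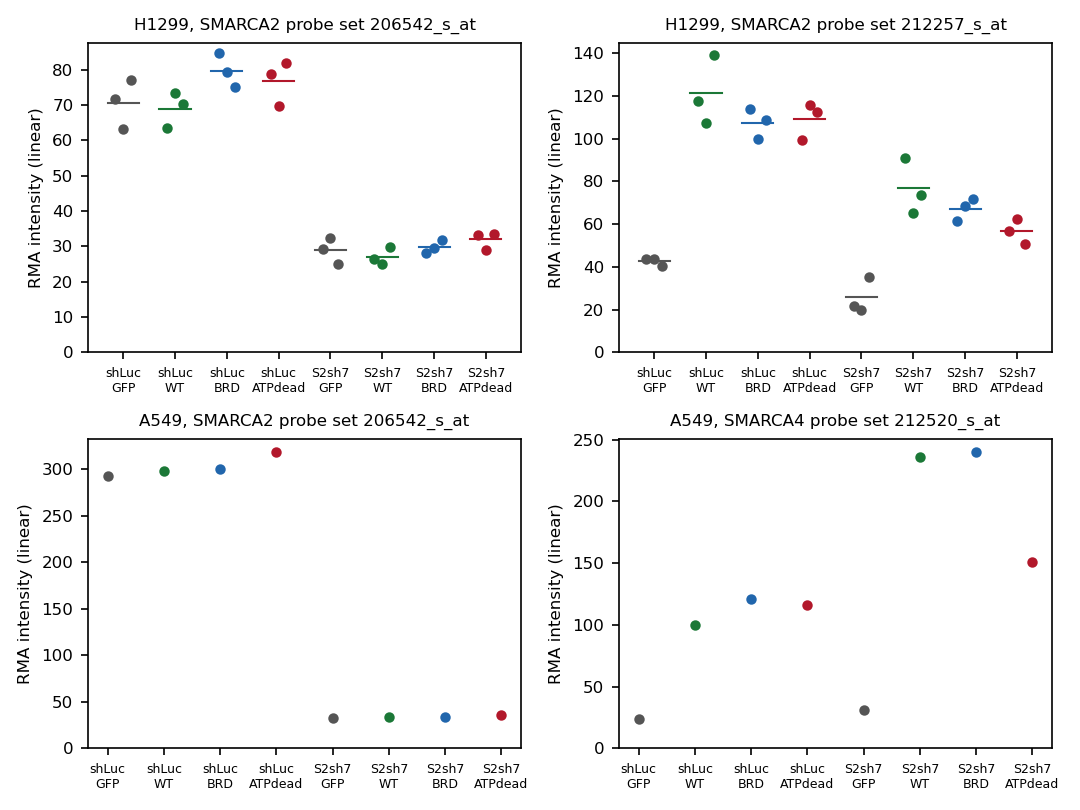
Linear RMA intensity of 3 target probe sets in each array. The upper panels show SMARCA2 in H1299 (3 arrays per group, line at the mean) and the lower panels SMARCA2 and SMARCA4 in A549 (1 array per group). The horizontal axis gives shRNA and cDNA.

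With GFP, S2sh7 raised SPP1, which encodes the secreted phosphoprotein osteopontin, by 3.37 log2 (SE 0.038, adjusted p = 5.93e-22), and CRH, a stress neuropeptide, by 3.01 (SE 0.067). EOMES, a developmental transcription factor, rose by 1.46, the collagen cross-linking enzyme LOX by 1.37, DUSP10 by 1.32, ID2 by 1.29, APOE by 1.21 and the WNT antagonist DKK1 to a similar extent (SE 0.040, adjusted p = 2.45e-14). ATF3, a stress-induced transcription factor, had the largest fall (log2 fold change -2.35, SE 0.054, adjusted p = 1.37e-16). The interferon-induced genes IFI27 (-2.23), OAS1 (-1.90), GBP1 (-1.76), IFI6 (-1.69) and IFI44 (-1.67) fell as well, as did KLF4 (-1.82) and the neuropeptide gene SPX (-1.80). By the rule for naming genes, the 3 S2sh7 arrays did not overlap the 3 shLuc arrays for any of these 16 genes. In limma, 4359 of 14695 genes were called, 1999 higher and 2360 lower, of which 10 and 56 changed at least 2-fold. With each array centred on its median, 3316 genes were higher and 1684 lower, so the balance of directions rests on the scaling.

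Interferon-stimulated genes, which respond to viral nucleic acids and to interferon, moved furthest as a group. Of 37 tested, 34 fell, none rose and 3 were not called, and 34 fell when adjusted over the list alone (median log2 fold change -0.67, camera adjusted p = 1.83e-63, adjusted p = 0.00016 with an estimated correlation). IFIT3 (-1.37), IFIT2 (-1.28) and the immunoproteasome subunit PSMB8 (-0.77) were among them. In the stress response list 24 of 31 genes fell, 3 rose and 4 were not called, with 25 lower and 3 higher adjusted over the list alone (median -0.38, adjusted p = 5.66e-23, adjusted p = 0.00389 with an estimated correlation). DDIT3 (-0.90), TRIB3 (-0.89), CHAC1 (-1.12) and the asparagine synthetase gene ASNS (-0.44), all driven by the integrated stress response, belong to it. Of 29 immediate early genes 14 fell, 6 rose and 9 were not called (14 lower and 7 higher adjusted over the list alone), with IER3 at -1.30 and EGR1 at -0.94. Their median was -0.10 (adjusted p = 7.81e-15), but adjusted p = 0.0588 with an estimated correlation.

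Genes of matrix and shape fell as groups. Among extracellular matrix genes 14 of 41 fell, 4 rose and 23 were not called, or 16 and 6 adjusted over the list alone (median -0.10, adjusted p = 9.33e-06). COL13A1 (-1.38), TGFBI (-1.36) and LOXL2 (-1.16) fell while LOX rose. Of 18 YAP and TAZ targets 11 fell, 2 rose and 5 were not called, or 12 and 2 adjusted over the list alone (median -0.17, adjusted p = 1.23e-09), among them FSTL1 (-0.89), AJUBA (-0.78) and the receptor kinase AXL (-0.67). Of 22 actin cytoskeleton genes 13 fell, 1 rose and 8 were not called, or 13 and 2 adjusted over the list alone (median -0.13, adjusted p = 1.66e-05), with tropomyosin TPM1 at -0.68. Of 25 mesenchymal genes 10 fell, 1 rose and 14 were not called, or 11 and 2 adjusted over the list alone (median -0.13, adjusted p = 0.0012), with SNAI2 at -1.06. These 4 lists kept adjusted p = 0.00968, 0.03, 0.00658 and 0.0113 with an estimated correlation. Epithelial genes had 4 lower, 3 higher and 18 not called of 25 (5 and 3 adjusted over the list alone, median -0.05, adjusted p = 0.0169), led by KRT7 (-1.30), KRT8 (-0.81) and KRT18 (-0.56). Inflammatory secreted genes had 9 lower, 3 higher and 11 not called of 23 (9 and 3 adjusted over the list alone, median -0.08, adjusted p = 0.00755), led by IL32 (-1.05) and PLAU (-0.73). Both lists lost the call, with adjusted p = 0.185 and adjusted p = 0.286 with an estimated correlation. For epithelial genes that estimate was -0.004, below the preset 0.01, so correlation does not account for the loss.

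Several further lists were not called by camera in this comparison. Mitotic genes rose in 11 of 35 cases and fell in 1, with 23 not called (14 and 3 adjusted over the list alone, adjusted p = 0.0969), for example the mitotic kinesin KIF20A by 0.18. DNA replication genes rose in 8 of 39 and fell in 2 (8 and 2 adjusted over the list alone, adjusted p = 0.0997), with the helicase subunit MCM6 at 0.29. SWI/SNF subunits other than the ATPases rose in 6 of 28 and fell in 2 (6 and 2 adjusted over the list alone, adjusted p = 0.256), with ARID1A at 0.21 and SMARCD3 at 0.36. Cholesterol genes showed 4 higher and 3 lower of 19 (4 and 3 adjusted over the list alone, adjusted p = 0.256), NRF2 targets 5 and 6 of 26 (5 and 6, adjusted p = 0.968), and hypoxia and glycolysis genes 8 and 11 of 30 (9 and 11, adjusted p = 0.968). Neuroendocrine genes showed 3 higher and 3 lower of 18 (3 and 3 adjusted over the list alone, adjusted p = 0.856), alveolar genes 0 and 1 of 13 (0 and 0, adjusted p = 0.48), and markers of leukocytes and endothelium 3 and 0 of 8 (3 and 0, adjusted p = 0.19). INSIG1, which holds back sterol synthesis, rose by 0.70, and ADM, a hypoxia-induced peptide, by 0.88.

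In H1299 cells expressing WT SMARCA2, SPP1 still rose with S2sh7, by 3.03 log2 (SE 0.038), CRH by 2.10, the neuronal cytoskeleton gene MAP2 by 1.44 and the collagenase MMP1 by 1.25. ATF3 (-1.55), SPX (-1.34), the lipase MGLL (-1.19) and ZNF568 (-1.16) fell. With BRD, SPP1 rose by 2.85, CRH by 2.40, SFT2D2 by 1.02 and DKK1 by 1.00, and ATF3 (-1.67), the matrix gene SPARC (-1.54), OAS1 (-1.49) and IFI27 (-1.49) fell. With ATPdead, SPP1 rose by 2.89, CRH by 2.64, LOX by 1.39 and EOMES by 1.37, and ATF3 (-2.10), OAS1 (-2.03), IFI27 (-1.82) and GBP1 (-1.62) fell. In limma 3895 genes were called with WT (2192 higher, 1703 lower), 3486 with BRD (1626 and 1860) and 4175 with ATPdead (2424 and 1751), with 22, 25 and 52 changed at least 2-fold. With arrays centred on their medians BRD gave 2531 higher and 1436 lower. Interferon genes fell in 26 of 37 cases with WT, 1 rising (29 and 1 adjusted over the list alone, median -0.25), in 34 with BRD (35 adjusted over the list alone, median -0.54) and in 34 with ATPdead (34 adjusted over the list alone, median -0.56). The adjusted p of interferon genes was 1.3e-11, 7.17e-46 and 5.07e-53, and 0.00411, 0.000217 and 0.000129 with an estimated correlation. Other lists fell with WT as well: the median was -0.21 for YAP and TAZ targets, -0.18 for actin cytoskeleton, -0.16 for immediate early and -0.31 for stress response genes (adjusted p = 4.31e-16, 5.38e-11, 1.82e-18 and 1.82e-18), all 4 called with an estimated correlation too (adjusted p = 0.00283, 0.000585, 0.00652 and 0.00301). Of the genes called with GFP, the same direction was called with WT for 1278 higher and 1297 lower genes, against 298 and 274 expected by chance, with BRD for 1115 and 1471 (expected 221 and 299), and with ATPdead for 1445 and 1432 (expected 330 and 281). These comparisons share no arrays with the GFP comparison.

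**Figure D2:**
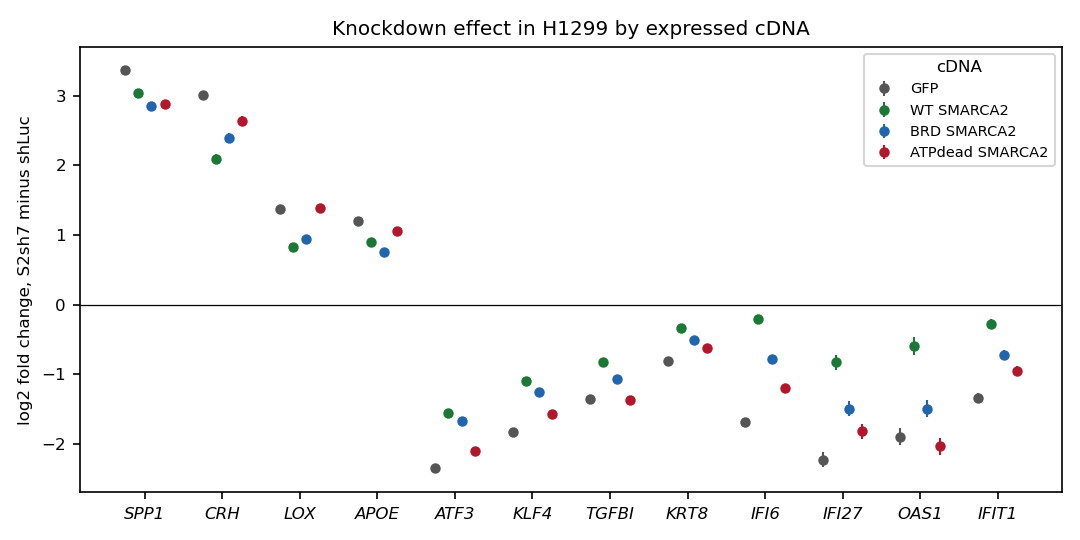
Log2 fold change, S2sh7 minus shLuc, of 12 genes in H1299 by expressed cDNA (GFP, WT, BRD or ATPdead SMARCA2), with the standard error from limma as bars; 3 arrays per group.

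The test of whether a cDNA changed the shRNA effect was the difference of the 2 knockdown effects. With WT SMARCA2 against GFP the effect on interferon genes was less negative: IFI6 by 1.48 log2 (SE 0.059, adjusted p = 1.04e-11), IFI27 by 1.40, OAS1 by 1.30, IFIT1 by 1.06, ISG15 by 0.89 and IFIT3 by 0.85. The effects on ATF3 (0.80), KLF4 (0.72), TGFBI (0.54) and KRT8 (0.47) were less negative too, and those on CRH (-0.91) and LOX (-0.54) less positive. IL10RB-DT (-0.63) and KIR2DL2 (-0.58), a divergent noncoding transcript and a natural killer cell receptor, were also called lower. In limma 335 genes were called, 268 higher and 67 lower. Scaling moved that split to 192 and 119 after repeated quantile normalization and to 128 and 181 with centred arrays. In the interferon list 26 of 37 genes were called higher and none lower (34 and 0 adjusted over the list alone, median 0.42, adjusted p = 3.82e-83, adjusted p = 2.6e-05 with an estimated correlation). Without shLuc GFP replicate 1, shLuc WT replicate 2, S2sh7 GFP replicate 1, shLuc WT replicate 1 or S2sh7 WT replicate 2 the count was 147, 169, 175, 200 or 210.

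With BRD SMARCA2 against GFP, 82 genes were called (57 higher, 25 lower), among them IFI6 (0.91, SE 0.059, adjusted p = 6.79e-08), IFI44 (0.75), IFI27 (0.73) and ATF3 (0.68), and on the lower side CRH (-0.61), ARID5B (-0.58), SPP1 (-0.52) and HLX (-0.52). Interferon genes were higher in 8 of 37 cases and lower in none (18 and 0 adjusted over the list alone, median 0.19, adjusted p = 5.07e-25, adjusted p = 0.00445 with an estimated correlation). Without S2sh7 GFP replicate 1 the count was 52. With ATPdead against GFP, 9 genes were called (7 higher, 2 lower), named in part by OASL (0.52), IFI6 (0.48), ZNF155 (0.47) and EGR1 (0.37) on the higher side, and by SPP1 (-0.48) and the bicarbonate transporter SLC4A7 (-0.32) on the lower. Interferon genes were higher in 2 of 37 cases (7 adjusted over the list alone, median 0.06, adjusted p = 3.95e-06), but adjusted p = 0.174 with an estimated correlation. Both scalings gave 3 higher and 3 lower. The count of 9 was 4 without shLuc GFP replicate 1, shLuc ATPdead replicate 1 or S2sh7 ATPdead replicate 2. It was 5 without shLuc GFP replicate 3, shLuc ATPdead replicate 2 or 3, or S2sh7 GFP replicate 1 or 3. The markers of leukocytes and endothelium, which a carcinoma line should lack, were called lower by camera in the interactions with WT, BRD and ATPdead. Their medians were -0.17, -0.16 and -0.19 (adjusted p = 0.00866, 0.00154 and 0.00252, or 0.0306, 0.0131 and 0.0356 with an estimated correlation), with 0 of 8 members called. All these interactions share the GFP arrays.

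Under S2sh7, ATPdead SMARCA2 differed from WT in LOX (0.75 log2 higher, SE 0.056, adjusted p = 1.2e-07), CRH (0.66), the lipid carrier APOE (0.60) and SLC44A3 (0.52). ATF3 (-0.998, SE 0.054, adjusted p = 2.69e-09), IFI27 (-0.93), OAS1 (-0.87), DDIT4 (-0.73), IFI6 (-0.65), KLF4 (-0.64) and TGFBI (-0.52) were lower. In limma 444 genes were called, 237 higher and 207 lower, and 174 and 274 with centred arrays. The SMARCA2 probe set that rose with each cDNA read 76.7 with WT, 67.1 with BRD and 56.7 with ATPdead under S2sh7. ATPdead against WT was -0.43 log2 there, not called (adjusted p = 0.208). It was -0.01 in a dimmer probe set that read higher with each cDNA under shLuc, without being called. A lower cDNA level with ATPdead is therefore not excluded. Interferon genes were lower in 8 of 37 cases and higher in none (17 and 0 adjusted over the list alone, median -0.13, adjusted p = 1.4e-18), and stress response genes in 10 of 31 (16 adjusted over the list alone, median -0.11, adjusted p = 5.34e-18). Both lists had adjusted p = 0.00484 with an estimated correlation. For immediate early genes the median (0.003) and the mean (-0.07) differed in sign, and the call (adjusted p = 0.00152) had adjusted p = 0.472 with an estimated correlation. Without S2sh7 ATPdead replicate 2, S2sh7 WT replicate 2 or S2sh7 WT replicate 1 the count was 240, 252 or 289. BRD differed from WT under S2sh7 in 9 genes, all lower, with ATF3 (-0.59, SE 0.054, adjusted p = 1.99e-05), TRAF1 (-0.40), MAFF (-0.31), IFI6 (-0.27), TRIB3 (-0.25), EGR1 (-0.23) and ASNS (-0.15) among them. Stress response genes were lower in 2 of 31 cases (17 adjusted over the list alone, median -0.11, adjusted p = 1.21e-22, adjusted p = 0.00283 with an estimated correlation). Interferon genes were lower in 1 of 37 cases (2 adjusted over the list alone, median -0.009) and were not called by camera (adjusted p = 0.226, or 0.677 with an estimated correlation). Under shLuc their median against GFP was -0.20 with WT and 0.05 with BRD. The gap between the WT and BRD knockdown effects on this list thus lay mostly in the shLuc lines. The count of 9 was 2 without S2sh7 WT replicate 1 and 1 without S2sh7 WT replicate 3, and repeated quantile normalization gave 8 higher and 18 lower.

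With the control shRNA, WT SMARCA2 raised the sialomucin gene PODXL by 0.72 log2 (SE 0.074, adjusted p = 2.92e-05), SPARC by 0.54, the matrix glycoprotein THBS1 by 0.53 and SPX by 0.50, while MAP2 (-0.64), OAS1 (-0.56), IFIT1 (-0.53), FAM13C (-0.49) and IFI6 (-0.47) fell. In limma 403 genes were called, 136 higher and 267 lower, a split of 190 and 188 after repeated quantile normalization and 204 and 152 with centred arrays. Interferon genes fell in 17 of 37 cases (23 adjusted over the list alone, median -0.20, adjusted p = 3.72e-26), and YAP and TAZ targets rose in 8 of 18 (10 adjusted over the list alone, median 0.15, adjusted p = 5.11e-16). Both had adjusted p = 0.00201 with an estimated correlation. Also called were actin cytoskeleton (4 of 22 higher, 6 adjusted over the list alone, median 0.07, adjusted p = 0.00011), immediate early (7 of 29 higher and 1 lower, 10 and 3 adjusted over the list alone, median 0.04, adjusted p = 2e-06) and cholesterol genes (4 of 19 lower, 7 adjusted over the list alone, median -0.05, adjusted p = 0.000357). The markers of leukocytes and endothelium, which a carcinoma line should lack, were called higher as well (1 of 8, 1 adjusted over the list alone, median 0.10, adjusted p = 0.0152). These 4 lists had adjusted p = 0.00878, 0.0262, 0.0351 and 0.033 with an estimated correlation. Without shLuc WT replicate 2, shLuc GFP replicate 3, shLuc GFP replicate 1 or shLuc WT replicate 1 the count was 134, 162, 166 or 190.

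BRD SMARCA2 with the control shRNA raised SPARC by 1.05 log2 (SE 0.141, adjusted p = 0.00048), PODXL by 0.66, IFITM1 by 0.62 and the matrix gene TNC by 0.59, and lowered CRH (-0.53), EGR1 (-0.37), RSKR (-0.36) and the histone gene H4C8 (-0.35). In limma 201 genes were called (127 higher, 74 lower). Extracellular matrix genes rose in 7 of 41 cases (15 higher and 1 lower adjusted over the list alone, median 0.11, adjusted p = 1.64e-12, adjusted p = 1.56e-05 with an estimated correlation). Camera also called mesenchymal (2 of 25 higher, median 0.04, adjusted p = 0.00444) and actin cytoskeleton genes (2 of 22 higher, median 0.05, adjusted p = 0.000467). Stress response genes were called lower (6 of 31, median -0.07, adjusted p = 3.31e-08). These 3 lists had adjusted p = 0.0317, 0.0243 and 0.049 with an estimated correlation. The count was 61, 79 or 83 without shLuc GFP replicate 1, 2 or 3, and 90, 126 or 72 without shLuc BRD replicate 1, 2 or 3. ATPdead SMARCA2 gave 18 genes (5 higher, 13 lower), with fibronectin FN1 (0.28), MEGF9 (0.24), NECTIN3 (0.19) and TMEM106B (0.15) higher, and the linker histone H1-4 (-0.59), GPAT2 (-0.27), SFI1 (-0.25) and EGR1 (-0.24) lower. That count was 0, 10 or 9 without shLuc GFP replicate 1, 2 or 3, and 0, 3 or 6 without shLuc ATPdead replicate 1, 2 or 3; repeated quantile normalization gave 19 higher and 22 lower.

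Across the 2360 genes that fell with GFP, the median log2 fold change was -0.14 with WT, -0.17 with BRD and -0.16 with ATPdead SMARCA2, and 91.3%, 96.1% and 94.2% of them kept the same sign. Across the 1999 that rose it was 0.16, 0.14 and 0.18. The 56 genes that fell at least 2-fold with GFP had medians of -0.80, -0.89 and -1.07, and the 10 that rose at least 2-fold had 0.93, 0.95 and 1.28. Because the genes were chosen on the GFP arrays, the GFP values (-1.29 and 1.31) are inflated, and the cDNAs are compared with each other. Under S2sh7 the 56 genes were lower with ATPdead than with WT by a median of -0.37 (fry adjusted p = 3.61e-11) and with BRD by -0.06 (adjusted p = 0.00639). The 10 genes were higher with ATPdead by 0.31 (adjusted p = 6.88e-11) and with BRD by 0.006, which was not called (adjusted p = 0.495). A score, the mean of the 10 genes minus the mean of the 56, was 2.26 with S2sh7 and GFP, 1.17 with WT, 1.27 with BRD and 1.93 with ATPdead (n = 3 each). With shLuc it was -0.68, -0.87, -0.90 and -0.68. The possible difference in cDNA level between ATPdead and WT under S2sh7, given above, applies to these comparisons too. Among WT, BRD and ATPdead under S2sh7 each pair of groups was fully separated, at an exact permutation p of 0.1, the smallest that 3 against 3 arrays can give. GFP against each cDNA also gave 0.1, but the genes were chosen on the GFP arrays, so that separation is partly fixed by the choice.

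**Figure D3:**
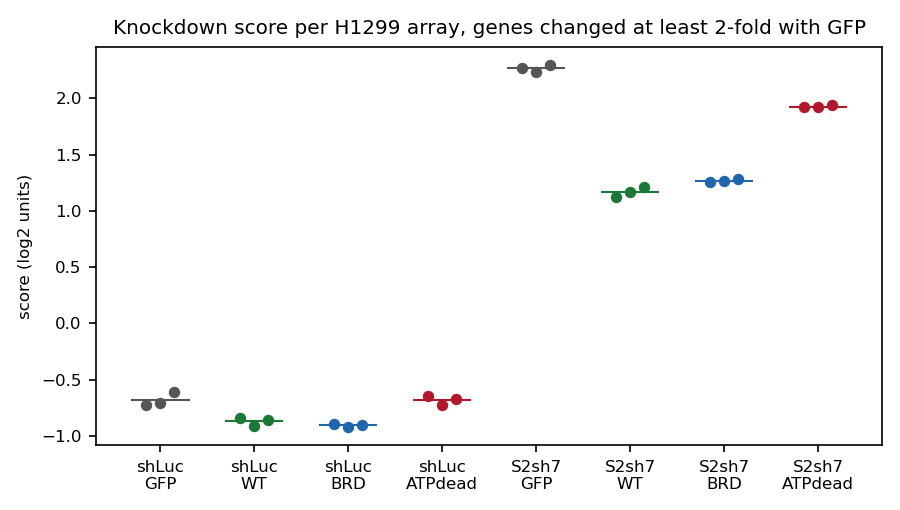
Score per H1299 array (mean log2 of the 10 genes that rose at least 2-fold with GFP minus the mean of the 56 that fell), by shRNA and cDNA; 3 arrays per group, line at the mean.

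In A549, SMARCA2 fell by -3.02 log2 over the 4 cDNA lines (SE 0.080, adjusted p = 0.0016), and in single pairs it was 9.06-fold lower with GFP, 8.58-fold with WT, 8.02-fold with BRD and 6.89-fold with ATPdead SMARCA4. S2sh7 raised the protease-like gene PRSS35 by 2.98 (SE 0.313, adjusted p = 0.0119), the retinoic acid hydroxylases CYP26B1 (2.91) and CYP26A1 (2.75), the cystathionine lyase CTH (2.86), the collagen gene COL3A1 (2.81), the glucose transporter SLC2A3 (2.77), GATA3 (2.73) and NIBAN1 (2.62). The largest falls were in TM4SF20 (-4.44, SE 0.737, adjusted p = 0.0236), ST6GAL2 (-4.03), TM4SF4 (-3.92), the retinol carrier RBP4 (-3.81), SLC17A3 (-3.62), KCNJ16 (-3.57), the tyrosine-degrading enzyme HGD (-3.50) and the tight junction gene CLDN2 (-3.45). By the rule for naming genes, each of these 16 genes had the same sign in 4 of 4 pairs. In limma 3098 genes were called, 1766 higher and 1332 lower, with 151 and 246 changed at least 2-fold. There is no replicate in A549, so the spread was the departure of the 4 pairs from a common effect, and a true difference between cDNAs counts as error. Without the GFP, WT, BRD or ATPdead pair the count was 101, 376, 1676 or 8.

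Of 30 hypoxia and glycolysis genes in A549, 12 fell, 3 rose and 15 were not called (19 and 3 adjusted over the list alone, median -0.29, adjusted p = 0.00259), including the kinase PDK1 (-1.15) and BNIP3 (-0.87). Of 19 cholesterol genes 7 fell, none rose and 12 were not called (10 and 1 adjusted over the list alone, median -0.25, adjusted p = 0.0212), including DHCR7 (-0.91) and LSS (-0.64). These calls were lost with an estimated correlation, with adjusted p = 0.595 and adjusted p = 0.798. The estimated correlation was 0.017 for hypoxia and glycolysis genes, near the preset 0.01, and 0.30 for cholesterol genes. That test also rests on the 3 residual degrees of freedom of the A549 fit. The lost calls are therefore not a sign of correlation alone. Camera called no other list given here. Interferon genes showed 5 higher and 2 lower of 37 (7 and 4 adjusted over the list alone), although their median was -0.17. A fall that differs in size between the pairs counts as error and is less easily called. Immediate early genes showed 9 higher and 5 lower of 29 (12 and 10), stress response genes 3 and 9 of 31 (4 and 10), and SWI/SNF subunits 7 and 0 of 28 (8 and 0). For inflammatory secreted genes the median (-0.19) and the mean (0.01) differed in sign.

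Single A549 pairs, given as values with no p, differed in size. The SD of the log2 differences over genes was 0.632 with GFP, 0.309 with WT, 0.296 with BRD and 0.614 with ATPdead SMARCA4, and 1171, 197, 182 and 1059 genes differed at least 2-fold. TM4SF20 differed by -6.35, -3.04, -2.48 and -5.90 in that order, and CYP26A1 by 3.94, 1.93, 1.36 and 3.77. The 688 genes at least 2-fold lower in the GFP pair had medians of -0.51 with WT, -0.46 with BRD and -1.40 with ATPdead, and the 483 higher genes 0.48, 0.42 and 1.33. Mitotic genes had a median of -0.26 with GFP and -0.55 with ATPdead, at percentiles 0.02 and 0 of 10000 random lists of the same size matched on mean expression, and 0.42 with WT and 0.48 with BRD, both at percentile 100. NRF2 targets had -0.65, -0.09, -0.10 and -0.59 for GFP, WT, BRD and ATPdead (percentiles 0, 0.51, 0.26 and 0). Interferon genes had -0.25, 0.01, -0.03 and -0.25 (percentiles 0.01, 39.2, 18.6 and 0). A percentile sets the list beside other genes of the same 2 arrays, ignores the correlation of its members and is no test of a cDNA or of the shRNA.

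**Figure D4:**
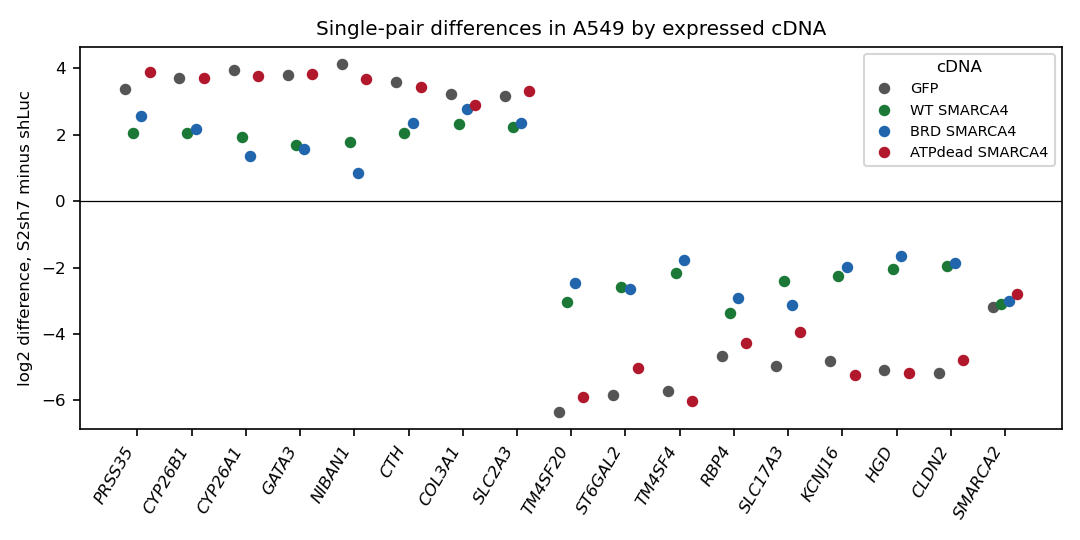
Log2 difference, S2sh7 minus shLuc, of 17 genes in each A549 pair by expressed cDNA (GFP, WT, BRD or ATPdead SMARCA4); 1 array per group, no error can be given.

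Over both shRNAs, 0 genes were called against GFP in A549 with WT, BRD or ATPdead SMARCA4 in limma, where 543, 803 and 281 had an unadjusted p under 0.05. This fit counts a cDNA effect that differs between the shRNAs as error. Even the SMARCA4 probe set that rose with the cDNAs was not called, at 2.50, 2.65 and 2.28 log2. A count of 0 therefore does not show that the cDNAs changed nothing. Mitotic genes were higher as a list with WT (median 0.44, adjusted p = 4.21e-10) and BRD (median 0.46, adjusted p = 1.77e-09), with 0 members called; adjusted p = 0.887 and adjusted p = 0.72 with an estimated correlation. Taken as single arrays, cDNA minus GFP differed at least 2-fold for 6, 2 and 9 genes with shLuc and for 643, 759 and 6 with S2sh7, for WT, BRD and ATPdead.

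Genes that rose in both lines, taking H1299 with GFP and A549 over the 4 cDNAs, included MAP2 (0.93 and 2.29 log2), FAT4, SFT2D2, GBX2, EPHA7, the histone genes H2BC12 and H2BC12L, and NR2F1. SMARCA2, SPX, TGFBI (-1.36 and -1.51), LOXL2 (-1.16 and -1.09), EMP1, MGLL, KRT80 and CCDC9B fell in both. The calls shared 430 higher genes (240 expected, Fisher exact p = 4.65e-39) and 353 lower genes (214 expected, Fisher exact p = 1.08e-24), and 428 genes were called in opposite directions (465 expected). The Fisher test takes genes as independent, so its p is too small where genes move together and does not measure the spread between samples. Over all genes the Spearman correlation of the A549 effect with that in H1299 was 0.064 with GFP, 0.054 with WT, 0.093 with BRD and 0.161 with ATPdead SMARCA2. SPP1, at 3.37 in H1299, differed by 0.07, -0.16, -0.25 and -0.22 in the A549 GFP, WT, BRD and ATPdead pairs. The 56 genes that fell at least 2-fold in H1299 had a median of -0.45 in A549 (camera adjusted p = 3.17e-05), or -0.57, -0.08, -0.18 and -0.53 in the GFP, WT, BRD and ATPdead pairs, while all 2360 that fell had -0.005 (adjusted p = 0.2). The 1999 that rose had 0.10 (adjusted p = 0.000271), and the 10 that rose at least 2-fold had 0.22 and were not called (adjusted p = 0.513). No value with an estimated correlation is given for these gene sets, so their camera p-values may be too small. Line and batch coincide, so levels were not compared between the lines.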

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

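The tests of the shRNA vectors, of a change in the control line alone, of knockdown strength, cDNA level and array scatter in A549, and of SMARCA2 RNA in H1299 were chosen only after the result was seen; the test of the SMARCA2 RNA was also reworded after its first outcome, from 1 probe set to every probe set raised by the cDNAs.

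The knockdown effect differed between H1299 with GFP and A549 over 4 cDNAs for 7 lists in a test of the difference itself, H1299 minus A549, by camera at the preset correlation of 0.01. The median differences were -0.661 log2 for interferon (camera adjusted p = 3.5e-12), -0.416 for immediate early genes (0.000778), -0.384 for YAP and TAZ targets (0.00869), -0.139 for the stress response (0.000923), 0.295 for cholesterol (0.000783), 0.282 for hypoxia and glycolysis (0.00869) and 0.153 for DNA replication (0.0217). With an estimated correlation, run on this difference after it was seen, all 7 calls were lost, with adjusted p = 0.106, 0.272, 0.505, 0.16, 0.186, 0.186 and 0.568 in the same order. Line and batch coincide in this difference and cannot be told apart. The type of cDNA differed too, but GFP was expressed in both lines. In the A549 GFP pair the medians were -0.246, 0.518, 0.315, -0.118, -0.295, -0.260 and -0.311 in the same order, against -0.672, -0.098, -0.173, -0.383, 0.020, 0.010 and 0.029 in H1299 with GFP. All 7 differed in the same direction as above, but with 1 array per A549 group this was not tested. Among probe sets with no single gene symbol (none or several), which no comparison used, 888 of 5247 were called in H1299 with GFP (16.9%) and 826 in A549 (15.7%). These are calls in data outside the main measurement, at a lower share than among tested genes (29.7% and 21.1%). No explanation was tested for these counts.

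Interferon genes fell with GFP and fell less with WT SMARCA2. A different response to the 2 shRNA vectors stays open for the smaller fall. Under S2sh7 alone the list was lower with ATPdead than with WT by a median of -0.129 (adjusted p = 0.00484 with an estimated correlation). For BRD against WT the median was -0.009 and the list was not called (camera adjusted p = 0.226). Lines that respond differently to the S2sh7 vector could also differ in this way, so this comparison cannot decide. A change in the control line alone is argued against by a rise of 0.227 from S2sh7 GFP to S2sh7 WT (0.182 to 0.326 over 9 array pairs), although the control line contributed, with a median of -0.196 for WT against GFP under shLuc. For the fall with GFP itself the vectors stay open: the A549 GFP pair also fell, by a median of -0.246, without a replicate. Separate derivation of the stable lines is untested and stays open, as does a biological effect of the WT cDNA.

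The A549 shRNA effect was smaller with WT and BRD than with GFP and ATPdead SMARCA4. Weaker knockdown in the WT and BRD lines was not seen. Their mean SMARCA2 log2 fold change lay at -0.0696 relative to the other pair of lines. With S2sh7 the SMARCA2 probe set used read log2 5.13, 5.47, 5.63 and 5.63 for GFP, WT, BRD and ATPdead, near background. A difference in the SMARCA2 RNA that remained is therefore not excluded. Scatter between single arrays is argued against by a ratio of 3.08 between the smaller SD of the WT and BRD lines against GFP under S2sh7 and the largest SD under shLuc. A lower cDNA level stays open: under S2sh7 the SMARCA4 probe set read -0.647 log2 in ATPdead relative to WT, although above GFP by 2.27, a lower bound because GFP read under log2 5. With 1 array per group the biological explanation, loss of ATPase activity, stays untested.

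Part of the H1299 shRNA effect remained with WT SMARCA2. Too little SMARCA2 RNA from the cDNA cannot be told apart, since the 2 probe sets that rose most with the cDNAs disagreed in the S2sh7 WT line relative to shLuc GFP. Under shLuc the first rose by 0.47, 0.41 and 0.53 log2 with WT, BRD and ATPdead. These rises were not called (limma adjusted p = 0.0609, 0.142 and 0.105). The first lay at -0.720 log2, which goes with the explanation. It read log2 4.97, under 5, so the size of this shortfall is uncertain and may be understated. The second lay at 0.837, which goes against it. Whether the second reads endogenous and cDNA transcripts alike is not known, which keeps the explanation open. An effect of the shRNA shared by both lines also stays open: genes that fell with WT in H1299 fell in both the WT and BRD pairs of A549 more often than all genes, by 7.35 percentage points (40.8% against 33.4%). No biological explanation was tested for what remained.

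Other splits of the same arrays bear on each count. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05; the real split gave the highest count in 1 of 10, with the real and highest other count at 4359 and 0 for the knockdown with GFP, 3895 and 0 with WT, 3486 and 2 with BRD, 4175 and 1 with ATPdead, 9 and 0 for BRD against WT, 444 and 3 for ATPdead against WT, and 403 and 0, 201 and 0, and 18 and 0 for WT, BRD and ATPdead under shLuc. The A549 knockdown had 8 splits, also too few, with 1 of 8 as high (3098, highest other 0). For the interaction with WT, 1 of 100 splits reached 335 (highest other 195), a share under 0.05. Mixed splits put differences between the groups into their own error, and splits of arrays cannot show the spread between separately derived lines. Chance is therefore not excluded by this share. For ATPdead, 3 of 100 reached 9, under 0.05 too, but the highest other split called 184. For BRD, 7 of 100 reached 82, and this share does not decide on chance either, since splits can carry a difference between the cDNAs. The highest other BRD split called 1074 and exchanged all S2sh7 arrays of the cDNAs, so that it measured the cDNA effect over both shRNAs, and the highest ATPdead split exchanged all shLuc arrays: both point to a structure of the samples, the cDNA lines themselves.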

How the results depend on the processing

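No alternative here was chosen only after the result was seen. Arrays limit the results by their number and by signal over background. Of 5919 values of named genes under alternatives other than leaving out arrays, 5614 kept direction and side of the threshold, 303 were weaker, 1 stronger and 1 reversed; of 976 list results 852 kept both and 124 were weaker, 54 of these with an estimated correlation. With 1 array or pair left out, 3217 of 3800 values of named genes kept both and 583 were weaker, as did 583 of 648 list results, with 65 weaker. Neither scaling changed the sign of any of 605 named values. This says little, since most named genes were chosen for called changes, and centring moved the medians of the comparisons only by -0.050 to 0.049 log2. SMARCA2 in WT SMARCA2 without knockdown reversed with the mean of all probe sets, to 0.28 (adjusted p = 0.0201) from -0.11, by construction, since this mean takes in the probe sets that rose with the cDNA; in BRD SMARCA2 without knockdown it became 0.29. The cause was not tested for the other shifts unless stated.

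Counts are given in the order knockdown with GFP, WT, BRD and ATPdead SMARCA2. A 2-fold threshold gave 66, 22, 25 and 52; interactions with WT, BRD and ATPdead 4, 0 and 0; BRD and ATPdead against WT under knockdown 0 and 0; WT, BRD and ATPdead without knockdown 0, 1 and 0; A549 knockdown 397, all by a stricter rule. Every probe set tested on its own gave 7173, 6225, 5860 and 6917, and 5773 in A549, more features by construction. Only the arrays compared, with fewer degrees of freedom, gave 2043 for knockdown with BRD, 148, 19 and 2 for interactions, 0 and 23 for BRD and ATPdead against WT, and 26, 1 and 0 without knockdown. The eBayes with trend and robust gave 532, 180 and 50 for interactions, 89 and 702 against WT, and 616, 415 and 196 without knockdown. Array weights gave 814, 451 and 239 without knockdown and 5138 in A549. No filter on dim genes gave 214 and 5 for interactions with WT and ATPdead, and 249 and 5 for WT and ATPdead without knockdown. The mean of all probe sets gave 54 and 3 for interactions with BRD and ATPdead. Log2 over 6 in 3 arrays gave 24 for BRD against WT and 47 for ATPdead without knockdown, and quantile normalization again 26 and 41.

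Replicate numbers did not pair the arrays (mean correlation of deviations -0.005); with a replicate block the interaction with ATPdead gave 5.

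The remaining knockdown effect on lower genes with WT, BRD and ATPdead was -0.80, -0.89 and -1.07 for genes called with a log2 fold change of at least 1, and -0.010, -0.031 and -0.020 for genes called in A549; on higher genes it was 0.93, 0.95 and 1.28, then 0.027, 0.031 and 0.052, and 0.141, 0.124 and 0.161 with the mean of all probe sets. The agreement of the lines, a Spearman correlation, was 0.0426 with every probe set, 0.0427 with no filter, 0.0936 with log2 over 6, 0.107 with quantile normalization again and 0.144 for genes called in either line.

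Leaving out 1 array gave 3496 to 4093, 3185 to 3526, 2776 to 3180 and 3433 to 3750 for knockdown with GFP, WT, BRD and ATPdead; 147 to 307, 52 to 73 and 4 to 12 for interactions; 1 to 8 and 240 to 377 for BRD and ATPdead against WT; 134 to 314, 61 to 126 and 0 to 10 for WT, BRD and ATPdead without knockdown; and, leaving out a pair, 8 to 1676 in A549.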

Other observations

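The test of the cDNA split in A549 was chosen only after the result was seen; the lists of the other 2 tests were prompted by the largest changes, which they leave out.

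It is a hypothesis that the labelled ATPase sets the A549 shRNA effect. The interaction of shRNA with the split of GFP and ATPdead against WT and BRD called 3205 genes, and the other two splits of the 4 cDNAs called 0 at most. The split was taken from the sizes of the pairs, already seen, and the other two put that difference into the error, so these counts restate it and do not test the hypothesis. With 3 splits the share cannot fall under 0.05, and lines and cDNA level remain confounded with the split.

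Several of the largest A549 falls are in genes of liver-type metabolism, so that a shared fall of such genes may be part of the effect. A list of 29 other liver-type genes had a median log2 fold change of -0.641 in A549 (camera adjusted p = 1.09e-07, equal to the unadjusted value for a single list), with 11 lower and 0 higher among called genes. With an estimated correlation the adjusted p was 0.187, so the list was called with the preset correlation only. The second test also rests on 3 residual degrees of freedom, so it does not show that correlation is the reason.

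Some zinc finger genes of chromosome 19 were among the called genes of the H1299 interactions, and a rise of that family with WT SMARCA2 was a second hypothesis. The other 190 tested members had a median of 0.0565 log2 in the interaction with WT (camera adjusted p = 0.314 over 12 comparisons), which does not decide it. In the knockdown with GFP the same genes had a median of -0.08 (adjusted p = 0.00309), with 57 lower and 11 higher. In the interactions with BRD and ATPdead the median was 0.04 (adjusted p = 0.0064) and 0.06 (adjusted p = 0.0574). Under the control shRNA the genes were lower than with GFP, by a median of -0.03 with BRD (adjusted p = 0.00571) and -0.04 with ATPdead (adjusted p = 0.00768). Under S2sh7 they were lower than with WT, by -0.04 and -0.03 (adjusted p = 0.00309 for both). These values were read with the preset correlation only.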
